A study of Mus musculus with 6 samples.

How the data were processed

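Gene expression was measured by RNA sequencing in 6 libraries from neoplastic mouse pancreas cells, 3 of them untreated (A, B and C) and 3 from cells exposed to TGF-b1 and then cultured further (A, B and C). Per the labels' protocols, RNA was isolated with an RNeasy kit, treated with DNase, and made into libraries with standard Illumina protocols. The submitters' processing notes name bcl2fastq, STAR, Picard, HTSeq and DESeq2, and the builds mm10 and GRCm38. The role, order and versions of these tools, the annotation release and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping antisense gene cannot be separated.

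The deposited matrix holds one signal value per gene and library for 41012 rows, of which 16099 were at 0 in every library. From the values, the signal in each column was a whole multiple of one step, with 100% of values whole at a tolerance of 0.01 reads, which is the pattern of gene counts divided by one size factor per library by the authors. The steps corresponded to size factors from 0.973 to 1.07. Dividing by the step recovered the whole reads, and the library totals were 25330107, 25853946 and 25959056 reads for untreated A, B and C and 27682669, 25836417 and 25184646 reads for TGF-b A, B and C. In untreated B, untreated C and TGF-b B the step lay so close to 1 read that the recovered reads nearly equal the deposited values. In 27 rows the gene symbol had been turned into a calendar date, and these rows were kept under that name. No columns of other samples were present. A count of 3 reads over a group served as the floor for genes at 0, and 3 reads in a single library corresponded to 2.81 to 3.08 normalized counts. Counting intervals were exact at the 95% level, and both intervals and floors cover counting error only, since the reads carry no molecular identifiers.

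The deposited values were used without rescaling. A pseudocount of 1 was added, log2 values were taken, and the 14645 genes with a mean of at least 10 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3, using a linear model with the treatment as its only term and moderated variances with a mean-variance trend. Fold changes are therefore on the log2(value + 1) scale, which understates the change of genes with low values. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. A second count required a change of at least 2-fold. Where a group held 0 reads, the fold is given as a bound against 3 reads over the group, and where it held 1 to 3 reads, as the ratio of normalized reads with its counting interval.

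The 31 gene lists, the rule for named genes, the tests of single genes and of lists, and all alternatives except one were fixed before the data were examined. Tests of patterns found in the data were added later. The lists covered epithelial and mesenchymal genes, signalling, metabolic and cell cycle programmes, pancreatic cancer subtypes and markers of other cell types. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the 30 lists with at least 3 tested members. Camera with a correlation estimated per list and fry, which tests whether a list's genes move on balance one way, were run beside it. With an estimated correlation camera uses only the few residual degrees of freedom of the 6 libraries, so it is the weaker test even at an equal correlation. The genes named are the 10 with the largest positive and the 10 with the largest negative fold change among those past the threshold, with a mean of at least 100 in the higher group, no overlap between the groups and a gene symbol that is not a predicted or clone name. To these were added up to 4 members of each list with the largest change, and a fixed set of genes of KRAS, p53 and TGF-beta signalling and epithelial-mesenchymal transition (EMT). Other list members are printed as examples where a list is described, and they were chosen after their values were seen. Members at 0 reads in a group were also placed at their bound, which left the median of each list as printed.

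Gene positions are those of GENCODE M21, which is built on GRCm38, and were matched by symbol for 13898 of the 14645 tested genes. The test was checked on simulated counts with each gene's mean over the 6 libraries and the real library sizes. Among the 50 genes changed at each size, limma recovered 66% at 1.2-fold, 80% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, and 4% of its calls were false. The simulation gave all genes a common spread beyond sampling noise, and limma called 175 genes in it, far fewer than in the data. These rates therefore do not carry over to the reported calls.

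The alternatives were another filter on low values, another pseudocount, another scaling between libraries, another variance model, the replicate letter as a block, each library left out in turn, a test against a fold of 2, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and other set tests. A correction for GC content and transcript length was added after the data were examined.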

Results

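The cells came from the pancreas of a KC mouse, in which Cre recombinase expressed from the Pdx1 promoter switches on an oncogenic Kras allele in the pancreatic epithelium. Their transcriptomes were compared between cells left untreated and cells given human recombinant TGF-b1 (500 pg/mL, 48 hours) and kept in culture 4 weeks longer. The comparison asks what transcriptional state the cells hold weeks after a transient exposure, and the series title calls that state quasi-mesenchymal. Each group held 3 libraries, described as technical replicates of one isolate, so that p-values measure the technical spread between libraries and not the variation between cultures or animals. The libraries held 25184646 to 27682669 reads assigned to genes, and 20186 to 20669 genes had at least 1 read in a library. Values are normalized counts, given as mean ± SD with n = 3 libraries per group unless stated otherwise. Replicate libraries were close, with a median within-group SD of 0.063 (log2) in untreated and 0.055 in TGF-b libraries. The 6 pairs of replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of 1.43 to 2.75, so each library was counted separately.

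Several of the genes with the largest gains had at most 3 reads in the untreated libraries. Olfm4, which encodes the secreted glycoprotein olfactomedin 4 (chromosome 14, 79984081 to 80023139, GRCm38), went from 0 reads in the untreated libraries to 9501 ± 203 and was at least 9474-fold higher. Ceruloplasmin, Cp, a copper-carrying ferroxidase (chromosome 3, 19957054 to 20009145), rose from 42.8 ± 3.6 to 96635 ± 303. The collagenase gene Mmp13 (chromosome 9, 7272514 to 7283331) rose from 14.3 ± 5.6 to 33075 ± 648, and the matrix glycoprotein gene Tnc (chromosome 4, 63959785 to 64047015) from 3 reads in all to 8642 ± 568, a ratio of 8599 with a counting interval of 2942 to 41698. The log2 fold changes of Cp and Mmp13 were 11.11 ± 0.047 (SE) and 11.15 ± 0.20, with limma adjusted p-values of 1.84e-19 and 3.71e-14.

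Among the other genes of this set, Has2, a hyaluronan synthase (chromosome 15, 56665627 to 56694539), had 1 untreated read against 2128 ± 178, a ratio of 6378 with a counting interval of 1144 to 251972. Chst11, a chondroitin sulfotransferase, had 2 untreated reads against 1875 ± 42, a ratio of 2804 (counting interval 776 to 23162). The mechanically gated channel gene Piezo2 had 3 untreated reads against 2022 ± 60, a ratio of 2017 (counting interval 690 to 9784), and its log2 fold change of 10.32 became 10.98 without untreated B. The WNT agonist gene Rspo3 (chromosome 10, 29452416 to 29535867) had 0 untreated reads and was at least 1181-fold higher, at 1185 ± 20. Saa3, an acute-phase serum amyloid gene with close paralogs that may share reads, rose from 2.34 ± 1.5 to 4332 ± 235, and the NADPH oxidase subunit gene Cybb from 1.34 ± 0.57 to 2661 ± 72.

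Among the genes with the largest losses, Ap1m2, which encodes the epithelial subunit of a clathrin adaptor (chromosome 9, 21294275 to 21312337), fell from 3389 ± 78 to 0 reads in the TGF-b libraries and was at least 3436-fold lower. Psapl1 (chromosome 5, 36204021 to 36206568) fell from 2144 ± 45 to 0 reads and was at least 2174-fold lower. The water channel gene Aqp5 (chromosome 15, 99590782 to 99594829) fell from 14294 ± 726 to 4.83 ± 3.1. Grhl2, a transcription factor of epithelial identity (chromosome 15, 37233036 to 37363569), fell from 2995 ± 55 to 2 reads in all, a ratio of untreated to TGF-b of 4555 with a counting interval of 1260.5 to 37615. With 2 reads of Tacstd2 and 3 each of Psca and Tmem30b left in the TGF-b libraries, the corresponding ratios were 3293 (counting interval 911 to 27194), 2678 (916 to 12990) and 2226 (761 to 10797). Prap1 fell from 10251 ± 348 to 6.90 ± 2.0, Cnfn from 2614 ± 148 to 1.36 ± 1.6, and Tspan1 from 3362 ± 84 to 2.27 ± 2.1. The log2 fold change of Tspan1 was −10.30, and −9.59 without TGF-b C.

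Over all genes, 11359 of the 14645 tested (77.6%) passed the limma threshold, 5768 higher and 5591 lower in the TGF-b cultures. At least 2-fold changes were found for 3904 genes, of which 1851 were higher and 2053 lower. The groups did not overlap for 79.9% of tested genes, against 10% if all 6 libraries were exchangeable. Technical replicates do not carry the variation between cultures, so this excess does not by itself point to the treatment. In 60 genes the mean reached at least 100 in the TGF-b libraries while the untreated libraries together held at most 3 reads, and in 46 genes the reverse held. Untreated B carried heart muscle transcripts (given with the markers of other cell types). Without it, 10995 genes passed the threshold, 10851 of them among the 11359, and 3898 changed at least 2-fold, 3825 of them among the 3904.

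**Figure D1:**
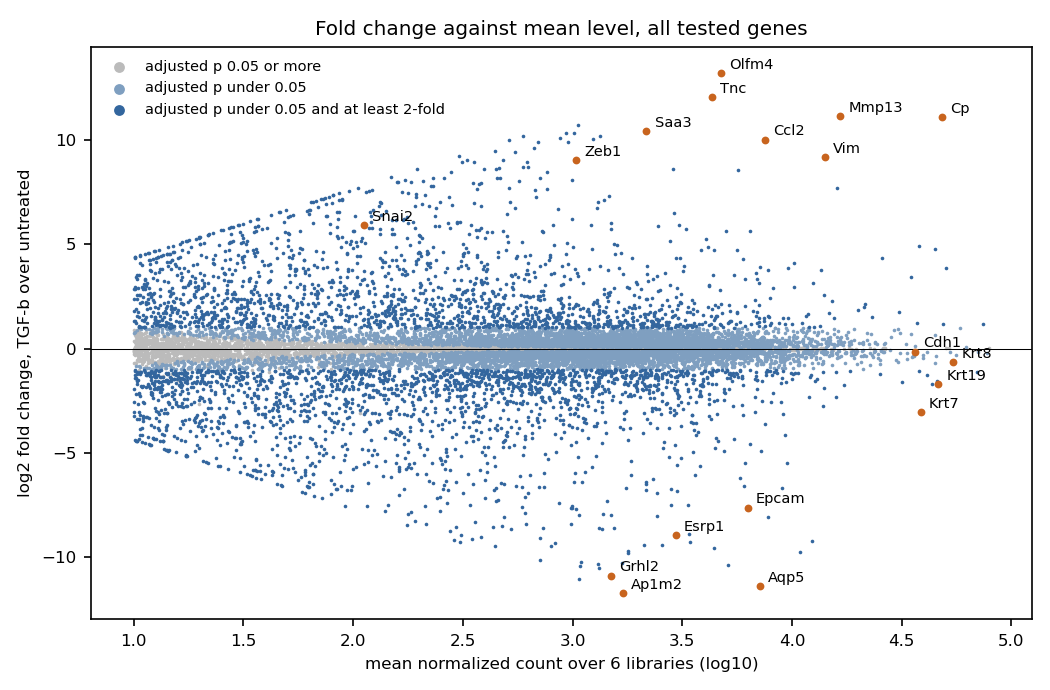
Log2 fold change (TGF-b over untreated, on the log2(value + 1) scale) against the log10 of the mean normalized count over 6 libraries, 1 point per tested gene, coloured by the limma adjusted p and by a change of at least 2-fold, with named genes in orange. Olfm4, Tnc, Mmp13 and Cp lie above 11 and Ap1m2 and Aqp5 below −11, while Cdh1 and Krt8 lie near 0 at high expression.

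The epithelial programme was lost unevenly. Of 36 epithelial junction and identity genes, 35 fell and 1 rose, with a median log2 fold change of −3.14 (camera adjusted p = 1.39e-12). This call was not kept with a correlation estimated for the list (adjusted p = 0.053 with an estimated correlation). The splicing regulator gene Esrp1 fell from 5896 to 11.1, the tight junction gene Cldn7 from 6812 to 13.7, the adhesion gene Epcam from 12516 to 62.6, and the trafficking gene Rab25 from 5090 ± 129 to 6.52 ± 1.7. E-cadherin, Cdh1, in contrast, fell from 38333 ± 380 to 34659 ± 701, a log2 fold change of −0.15 ± 0.023 (SE; limma adjusted p = 8.62e-05). The keratin genes Krt18 and Krt8 kept 77.9% and 63.7% of their untreated level, Krt19 kept 30.6%, and Krt7 kept 12.2%. The member that rose was Ehf, an epithelial ETS factor gene, from 10818 to 18195.

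Mesenchymal genes rose in the same libraries. Of 23 tested members of the mesenchymal list, 18 rose, 4 fell and 1 did not pass, with a median log2 fold change of 3.68 (camera adjusted p = 0.000322, and adjusted p = 0.15 with an estimated correlation). Vimentin, Vim, an intermediate filament gene (chromosome 2, 13573927 to 13582826), rose from 47.5 ± 8.4 to 28254 ± 349. Fibronectin, Fn1, rose from 3215 to 86501, and N-cadherin, Cdh2, from 99.0 to 3103. Fstl1 had 6 reads in the untreated libraries and a mean of 2468 ± 53 in the TGF-b libraries, and its log2 fold change of 10.07 was 10.76 without untreated B and 9.47 without untreated C. The list did not move as a whole, since the ectonucleotidase gene Nt5e fell from 5582 ± 224 to 50.6 ± 3.0, Tpm2 from 2249 to 116, Col5a1 from 714 to 133, and Col3a1 from 20.9 ± 27 to 1 read in all, a ratio of untreated to TGF-b of 64.1 with a counting interval of 11.1 to 2571. Col1a1 had 33 reads in the untreated libraries against a mean of 73.2 ± 3.0, and the untreated levels of Col1a1 and Col3a1 depended on single libraries. The log2 fold change of Col1a1 was 3.73, 4.91 without untreated B and 2.48 without untreated C, and it missed the threshold with DESeq2 (adjusted p = 0.0645) and with robust variances in limma (adjusted p = 0.0557), in a range of 6.41e-06 to 0.0645 over all alternatives. That of Col3a1, which the pseudocount holds below the ratio, was −3.39, and −2.39 without untreated B. The smooth muscle gene Tagln stood at 131 and 144, and Acta2, Postn and Mmp2 were below the level needed for a test.

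Transcription factors of EMT rose almost throughout the list, with 11 of 12 tested members higher, 1 lower, and a median of 1.92 (camera adjusted p = 0.000868, and adjusted p = 0.15 with an estimated correlation). Zeb2 rose from 1.33 ± 2.3 to 1331 ± 65 and Snai2 from 2.68 ± 0.60 to 221 ± 14. Zeb1 and Twist1 each had 9 reads in the untreated libraries and means of 2072 ± 14 and 102 ± 9.3 in the TGF-b libraries. Snai1 had 3 untreated reads against 64.7 ± 9.0, a ratio of 64.2 with a counting interval of 21.7 to 314. The 4 reads of Zeb2 in the untreated libraries gave a log2 fold change of 9.61, and 10.38 without untreated B. The member that fell was Foxc1, from 198 to 80.4.

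**Figure D2:**
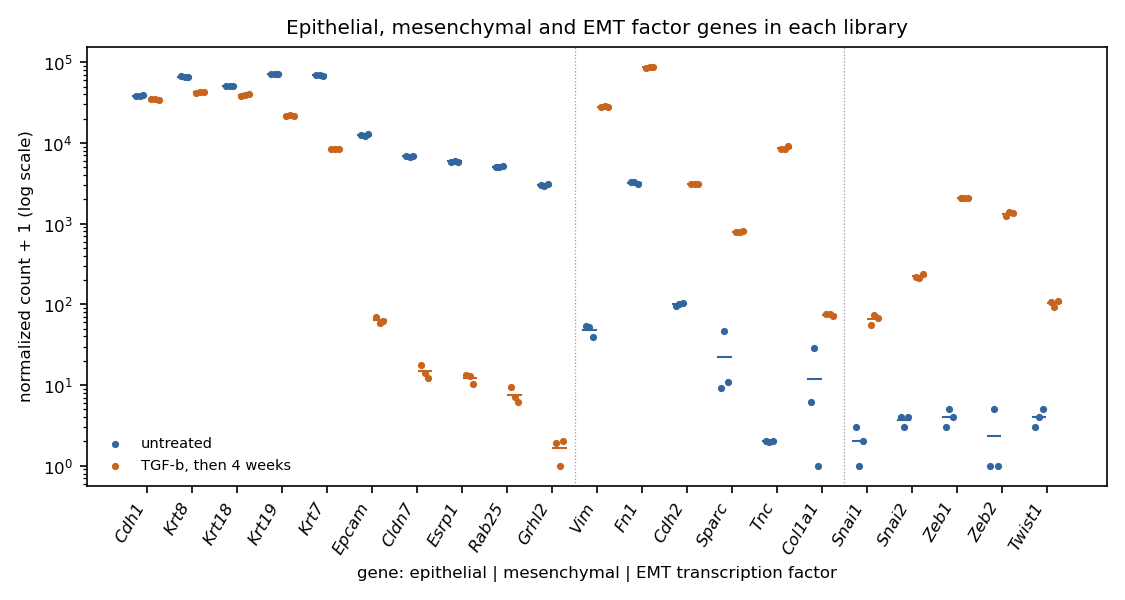
Normalized count + 1 on a log scale for epithelial, mesenchymal and EMT transcription factor genes, 1 point per library (3 untreated in blue, 3 TGF-b in orange) with a bar at each group's mean. Cdh1, Krt8 and Krt18 stay at means of 34659, 42233 and 39550 in TGF-b libraries, while Epcam, Cldn7, Esrp1, Rab25 and Grhl2 fall below 100. Vim, Zeb1 and Zeb2 rise from below 100 to above 1000, and Fn1 rises from a level already above 1000.

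Components of the TGF-beta pathway itself were higher weeks after the exposure. Of 30 tested ligands, receptors and transducers, 23 rose, 6 fell and 1 did not pass (median 0.85, camera adjusted p = 0.000876, and adjusted p = 0.15 with an estimated correlation). The activin subunit gene Inhba rose from 25.1 ± 1.1 to 1955 ± 4.1, Ltbp2, which binds matrix microfibrils, from 121 ± 22 to 6487 ± 78, Tgfb3 from 93.3 ± 2.7 to 3009 ± 62, and Tgfb1 from 520 to 2134. The BMP antagonist gene Grem1 had 0 untreated reads and was at least 34.7-fold higher. The receptor genes went opposite ways, Tgfbr1 rising from 3464 ± 181 to 10244 ± 71 and Tgfbr2 falling from 8416 ± 27 to 3431 ± 50. Smad4 rose from 3006 ± 32 to 3558 ± 42, a log2 fold change of 0.24 ± 0.025 (SE).

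Classical TGF-beta target genes moved both ways. Of 27 tested targets, 17 rose, 8 fell and 2 did not pass, or 17 and 9 when adjusted over the list alone (median 0.33, camera adjusted p = 0.14). Bambi rose from 36.1 to 270.2 and Rhob from 1717 to 7191, but the laminin gene Lamc2 fell from 12320 ± 236 to 507 ± 36 and Serpine1, the plasminogen activator inhibitor gene, from 26765 to 22388. Of 15 tested integrin genes, 10 rose and 5 fell (median 1.09, camera adjusted p = 0.14). Itga9 had 3 untreated reads against 966 ± 11 (ratio 963, counting interval 329 to 4671), Itga5, a fibronectin receptor subunit, rose from 881 ± 28 to 10062 ± 199, and Itgb6 fell from 2602 ± 83 to 225 ± 15. The integrin list passed the threshold with camera in edgeR on the recovered reads (adjusted p = 0.00306) and without the filter on low values (adjusted p = 0.0287), and the target list passed without the filter (adjusted p = 0.0496). Over all camera alternatives the adjusted p ranged from 0.00306 to 0.491 for integrins and from 0.0496 to 0.549 for targets. Of 25 matrix proteases and inhibitors, 17 rose, 6 fell and 2 did not pass (median 1.05, camera adjusted p = 0.016, and adjusted p = 0.15 with an estimated correlation). The stromelysin gene Mmp3 rose from 1.35 ± 1.6 to 788 ± 20, Mmp10 from 1 read in all to 320 ± 9.2 (ratio 956, counting interval 171 to 37815), and Timp1, a protease inhibitor gene, from 52.1 to 1052, while Mmp15 fell from 6340 to 690.

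Secreted cytokines and chemokines were higher in most cases. Of 27 tested, 19 rose, 6 fell and 2 did not pass (median 1.74, camera adjusted p = 0.00148, and adjusted p = 0.15 with an estimated correlation). The monocyte attractants Ccl2 and Ccl7 rose from 13.7 ± 2.9 to 15059 ± 391 and from 0 reads to 1028 ± 83, at least 1022-fold for Ccl7. Csf1 rose from 210 ± 17 to 7908 ± 124, Cxcl5 from 6382 to 94147, and Csf2, which encodes GM-CSF, from 64.2 ± 1.2 to 196 ± 8.8. Il1a fell from 1989 ± 75 to 9.59 ± 1.9.

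Interferon response and antigen presentation genes also rose. Of 30 interferon response genes, 26 rose, 3 fell and 1 did not pass (median 1.29, camera adjusted p = 3.29e-05, and adjusted p = 0.42 with an estimated correlation). Gbp2 rose from 8.05 ± 2.8 to 1357 ± 56 and Ifit3 from 37.8 ± 4.7 to 563 ± 91. Isg20 fell from 4199 to 913 and Mx1 from 351 to 110.4. Of 20 genes of MHC class I antigen presentation, 17 rose and 3 did not pass (median 1.02, camera adjusted p = 3.29e-05, and adjusted p = 0.15 with an estimated correlation). The immunoproteasome gene Psmb8 rose from 15.7 ± 7.9 to 285 ± 23 and B2m from 2373 to 9869, while the heavy chain genes H2-K1 and H2-D1 stood at 10940 and 11060 in untreated and 11170 and 10772 in TGF-b libraries. Reads of the Gbp, Ifit and H2 families can be shared between near-identical copies, so the split between members is uncertain.

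The quasimesenchymal tumour list of Collisson and colleagues had 6 members higher, 8 lower and 1 not past the threshold (camera adjusted p = 0.72). Its median log2 fold change was −0.17 and its mean 0.045, so they differ in sign. Twist1, Lox (7.03 ± 2.0 to 76.4 ± 6.2) and Gpm6b (499 ± 27 to 3624 ± 82) rose, while Nt5e and the mitotic gene Hmmr (954 to 347) fell. The classical tumour list had 3 members higher and 11 lower (median −2.03, camera adjusted p = 0.00421, and adjusted p = 0.196 with an estimated correlation). Tmem45b fell from 5964 ± 152 to 50.8 ± 3.5, Erbb3 from 5366 to 148, and the mucin gene Muc13 rose from 0 reads to 162 ± 9.8, at least 162-fold. All 16 tested basal and squamous genes fell (median −4.79, camera adjusted p = 3.56e-07, and adjusted p = 0.065 with an estimated correlation), among them Ly6d from 3568 ± 233 to 3.57 ± 1.9 and S100a14 from 15492 ± 302 to 56.2 ± 1.6.

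Among ductal and pancreatic progenitor genes, 7 rose, 11 fell and 2 did not pass (camera adjusted p = 0.31), with a median of −0.37 and a mean of 0.23, which differ in sign. Osteopontin, Spp1, rose from 2455 ± 218 to 73538 ± 1676, Bicc1 from 29.5 ± 4.2 to 11342 ± 234 and Sox9, a ductal transcription factor gene, from 41.8 ± 11 to 877 ± 36. The transcription factor gene Pdx1 stood at 1379 and 1324, and the chloride channel gene Cftr fell from 643 to 76.2. Of 13 gastric-type genes of precursor lesions, 10 fell and 3 rose (median −1.65, camera adjusted p = 0.028, and adjusted p = 0.196 with an estimated correlation). Muc1 fell from 18490 ± 354 to 411 ± 3.3, while the tuft cell gene Dclk1 rose from 3.67 ± 2.1 to 1529 ± 63 and the trefoil gene Tff2 from 14.03 ± 2.5 to 661 ± 44. Cancer stem cell markers split into 9 higher, 6 lower and 1 not past the threshold (median 0.35, camera adjusted p = 0.42), with Lgr5 rising from 9.07 ± 4.5 to 143 ± 23 and Kit falling from 235 ± 34 to 26.1 ± 8.5.

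Cell cycle genes fell together. All 25 G1/S and DNA replication genes were lower (median −1.13, camera adjusted p = 1.54e-07, and adjusted p = 0.24 with an estimated correlation), as were all 25 G2/M and mitosis genes (median −1.45, camera adjusted p = 7.15e-08, and adjusted p = 0.42 with an estimated correlation). The proliferation marker Mki67 fell from 5802 ± 571 to 1520.5 ± 65, Ccna2, which encodes cyclin A2, from 1983 ± 250 to 495 ± 18, and Rrm2, a ribonucleotide reductase subunit gene, from 9207 ± 433 to 2714 ± 166. The p53 target list had 12 members higher, 5 lower and 3 not past the threshold (median 0.26, camera adjusted p = 0.14), with the death receptor gene Fas rising from 23.8 ± 1.6 to 321 ± 19 and Cdkn1a, the p21 gene, at 10171 and 9801. Trp53 rose from 3017 ± 15 to 4184 ± 67 and Kras from 2737 ± 116 to 3643 ± 62, each summed over its alleles. Cdkn2a stood at 640 ± 14 and 676 ± 40 and did not pass (log2 fold change 0.08, limma adjusted p = 0.186). It passed after upper-quartile rescaling (adjusted p = 0.0479), quantile normalization (adjusted p = 0.0429) and a correction for GC content and length chosen after seeing the data (log2 fold change 0.28, adjusted p = 0.00023). Over all its alternatives the adjusted p of Cdkn2a ranged from 0.00023 to 0.58.

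Apoptosis regulators of the BCL2 family and related genes had 10 members higher, 11 lower and 1 not past the threshold (camera adjusted p = 0.98), with Bmf rising from 464 ± 46 to 2013 ± 17 and Bcl2l11 falling from 1229 to 551. Their median was −0.074, their mean 0.0080, and camera and fry gave opposite signs. RAS-MAPK feedback and output genes had 16 higher, 8 lower and 1 not past the threshold, or 17 and 8 when adjusted over the list alone (median 0.44, camera adjusted p = 0.13). Spred1 and Spry4 rose from 1578 ± 61 to 3818 ± 58 and from 398 to 944, while Dusp6 fell from 10974 to 6436 and Fos from 3916 ± 142 to 1012.5 ± 32. The list passed without the filter on low values (adjusted p = 0.0416, in a range of 0.0416 to 0.273 over the camera alternatives). Of 18 WNT ligands and targets, 9 rose, 7 fell and 2 did not pass (median 0.78, camera adjusted p = 0.45). Axin2, a feedback target, rose from 5.04 ± 3.1 to 350 ± 24 and Wnt5a from 8.37 ± 2.1 to 588 ± 11, whereas Wnt7a fell from 1397.5 ± 37 to 13.3 ± 3.7. YAP/TAZ targets had 13 higher, 8 lower and 1 not past the threshold (median 0.23, camera adjusted p = 0.29), with the receptor gene Axl rising from 2317 ± 51 to 18163 ± 211 and Igfbp3 falling from 22236 to 5914.

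Metabolic and stress genes were mostly lower. Of 25 cholesterol and fatty acid synthesis genes, 24 fell and 1 rose (median −0.69, camera adjusted p = 3.35e-07, and adjusted p = 0.23 with an estimated correlation). The desaturase genes Scd1 and Scd2 fell from 5967 ± 219 to 1840 ± 41 and from 68279 ± 968 to 23515 ± 294, and Pcsk9, which lowers the LDL receptor, rose from 1395 ± 150 to 3502 ± 137. Of 24 glycolysis and hypoxia genes, 20 fell and 4 rose (median −0.32, camera adjusted p = 0.00274, and adjusted p = 0.497 with an estimated correlation). The hypoxia-responsive genes Ndrg1 and Car9 fell from 12114 ± 230 to 1470 ± 152 and from 6912 ± 97 to 2124 ± 133, while Hk2, a hexokinase gene, rose from 4794 to 7626. Of 20 heat shock and unfolded protein stress genes, 15 fell, 4 rose and 1 did not pass (median −0.60, camera adjusted p = 0.017, and adjusted p = 0.43 with an estimated correlation), and this list missed the threshold with camera in edgeR on the recovered reads (adjusted p = 0.115, in a range of 0.00381 to 0.432 over the camera alternatives). Trib3, a target of the integrated stress response, fell from 1708 ± 257 to 228 ± 6.9, and Xbp1, a factor of the unfolded protein response, rose from 3964 to 9045.

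**Figure D3:**
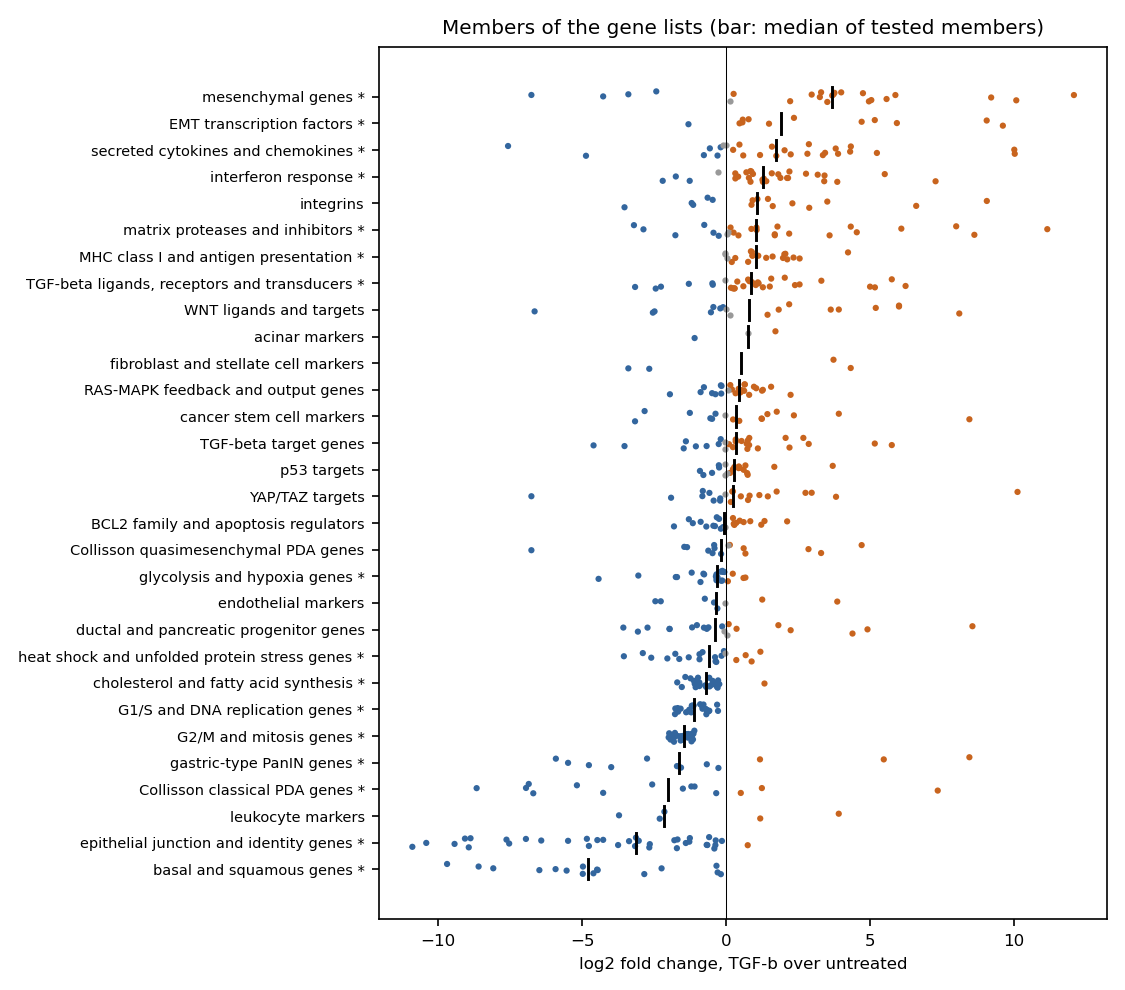
Log2 fold change (TGF-b over untreated, on the log2(value + 1) scale) of every tested member of 30 gene lists, orange for members past the threshold and higher, blue for those past it and lower, grey for the rest, with a black bar at the list's median and a star where the camera adjusted p passed. Epithelial and basal lists lie to the left with medians of −3.14 and −4.79, and mesenchymal genes to the right with a median of 3.68.

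Markers of other cell types were low or moved in different directions. Only 4 of 15 fibroblast and stellate cell markers reached the level for a test, 2 higher and 2 lower (camera adjusted p = 0.87), and the complement gene C3, which epithelial cells also express, rose from 2442 ± 225 to 48851 ± 1637. Of 5 tested leukocyte markers, 2 rose and 3 fell (camera adjusted p = 0.54), with Itgam at 8.36 ± 4.5 and 128 ± 5.5 and Cd68 at 1028 ± 25 and 232 ± 5.1. Of 8 tested endothelial markers, 2 rose, 5 fell and 1 did not pass (camera adjusted p = 0.29), with Sox17 at 3068 ± 133 and 636 ± 28. Acinar markers had 3 tested members, 1 higher, 1 lower and 1 not past the threshold (camera adjusted p = 0.84), and none of 14 endocrine markers reached the level for a test.

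Untreated B stood apart from the other untreated libraries in heart muscle transcripts. The cardiac myosin gene Myh6 had 646 normalized counts there and 0 reads in each of the other 5 libraries, and Nppa, Mb and Actc1 stood at 118, 97.4 and 54.7 against at most 1.02, 3.06 and 0. In this library 44 genes with at least 8 reads exceeded 3 times the mean of the other untreated libraries (binomial adjusted p under 0.01, which covers counting error only), with an excess of 0.00848% of its normalized counts, against 6 genes in TGF-b C, 1 in untreated C and 0 in the others. Col3a1 and Dcn of the fibroblast list were highest in this library as well, and the log2 fold change of the endothelial marker Kdr was 3.86, and 4.58 without it.

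**Figure D4:**
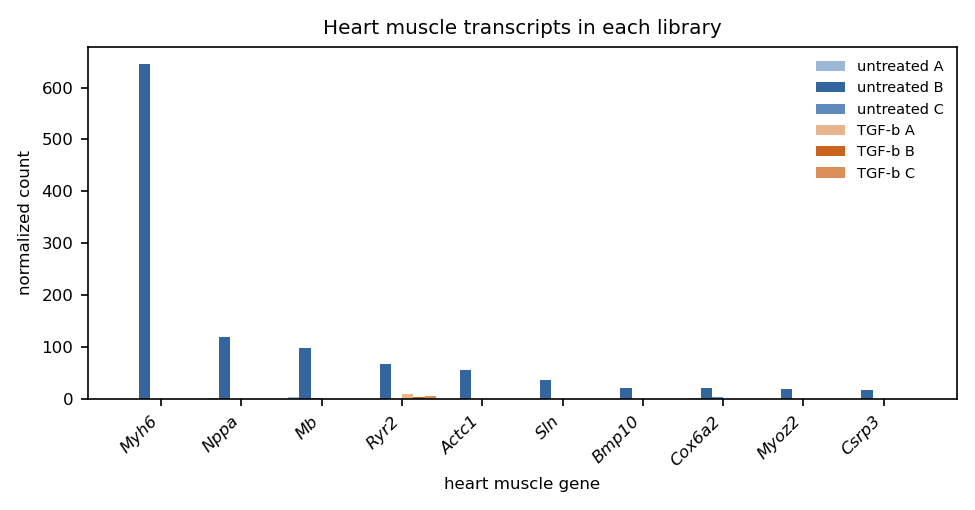
Normalized counts of heart muscle genes in the 6 libraries, 1 bar per library (untreated in blues, TGF-b in oranges), on an axis that starts at 0. Myh6 reaches 646 in untreated B and is at 0 in the other 5 libraries.

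With the preset correlation 16 of the 30 tested lists had a direction, 7 higher and 9 lower, and none passed with an estimated correlation. Adjusted over the list alone, the counts of members were those given above, apart from the lists of TGF-beta targets and RAS-MAPK genes.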

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

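The correction for GC content and transcript length was chosen after seeing the data, and the other alternatives were planned. The counts of changed genes and of genes changed at least 2-fold stayed within 1.5 times of the reported ones under every alternative. Leaving out each library in turn gave 10921 to 11030 changed genes and 3874 to 3940 changed at least 2-fold, and 16 lists had a direction each time. The other settings gave 9946 (mean of at least 50) to 12662 changed genes (no filter on low values), and 2828 to 5501 changed at least 2-fold under the same 2 settings, as the number of genes tested changed. On the recovered reads, edgeR called 11478 genes, of which 11297 were among the 11359, and DESeq2 called 10618, of which 10612 were. Rescaling by the median of ratios divided all 6 libraries by one common factor, 1.0046, and so tests nothing. The share of higher among changed genes was 50.8% as deposited, 54.3% after upper-quartile rescaling and 52.8% after quantile normalization. The letters A, B and C showed no clear pairing of the libraries. The deviations of same-letter libraries correlated at 0.0056, −0.0093 and 0.014 across genes. TGF-b A and TGF-b C correlated best with the untreated library of their letter, and TGF-b B with untreated A (0.023). All combinations lay between −0.025 and 0.023, too small to show or exclude a pairing. With the letter as a replicate block, 11341 genes changed, 5751 higher and 5590 lower, 3913 of them at least 2-fold, 11230 were shared with the reported calls, and 16 lists had a direction, with no named gene or list changing its call. The number of lists with a direction depended on the set test. It was 0 when the correlation was estimated per list, and 29 with fry, which does not compare a list with other genes. A higher correlation does not account for every lost call. The estimate was 0.012 for epithelial genes and −0.047 for EMT transcription factors, near or below the preset 0.01, but 0.75 for G2/M genes. With an estimate, camera also refers its statistic to the few residual degrees of freedom of the 6 libraries. For epithelial genes the unadjusted camera p went from 4.62e-14 to 0.00178 at nearly the same correlation. A call lost this way therefore need not reflect correlation within the list. The BCL2 family list changed sign with fry, higher at an adjusted p of 0.00163. Of the 2569 values of the 136 named genes under alternatives, 2564 kept their direction and side of the threshold, Col1a1 lost it under 2 settings, Cdkn2a gained it under 3, and 0 reversed. Most of these genes were named because they passed the threshold with a large change, so few could lose it. The values also include those of the median-of-ratios rescaling. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave 11359 genes, the real one, and the highest of the others gave 0 with limma, 19 at an unadjusted p under 0.05, and 0 with edgeR. With 10 splits no share under 0.05 can be reached. The other splits also mix technical replicates of both groups, so any difference between the cultures enters their within-group spread. Their low counts therefore do not bear on what made the cultures differ. Genes with few reads in one group are limited by depth, since 3 reads amount to 2.81 to 3.08 normalized counts in a library.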

Other observations

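The tests of cell mixtures, fibroblasts, heart genes, mixing between libraries, chromosome-scale changes and neighbours without predicted or family names, and the genes and pairs named in the next 2 paragraphs, were chosen after the results were seen. The random lists for cell cycle genes had no prediction written beforehand. The other tests in this part were written down before their results were seen.

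Genes of the imprinted Dlk1-Meg3 region on chromosome 12 (109452823 to 109749460, GRCm38) were higher in the TGF-b libraries, but the region as a whole was not tested. Its non-coding RNA genes Meg3 and Rian stood at 0.340 ± 0.59 and 2.34 ± 0.56 normalized counts in untreated and 657 ± 22 and 408 ± 20 in TGF-b libraries (SD, n = 3). Mirg and the Notch-like ligand gene Dlk1 had 0 untreated reads and stood at 21.3 ± 3.5 and 15.0 ± 6.2 in TGF-b libraries. Dlk1, below the mean of 10 over the 6 libraries needed for a test, and Rtl1, with 1 and 2 reads in the groups, were not tested. On chromosome 4, Mtap and the cell cycle inhibitor gene Cdkn2b rose from 3618 ± 58 to 7270 ± 42 and from 965 ± 39 to 2072 ± 62, while Cdkn2a, which lies between them, stood at 640 ± 14 and 676 ± 40.

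Genes changed at least 16-fold lay next to another such gene changed in the same direction more often than expected from a random order. Twist1 and the next tested gene Hdac9 had log2 fold changes of 4.70 and 6.98, Gli3 and Inhba 4.75 and 6.23, Cd109 and the collagen gene Col12a1 4.31 and 7.34, and the lost genes Tmem30b and Prkch −10.25 and −4.19. The hypothesis that neighbouring genes may change together was tested by permuting the order of the 13898 placed genes 10000 times. Without pairs that share a name stem, 77 neighbouring pairs were found against a permuted mean of 21.7 and a highest of 40 (permutation p = 0.0001, one-sided, the smallest that these permutations can give). Among protein-coding neighbours at least 10 kb apart, which argues against reads shared between adjacent genes, 44 pairs were found against a permuted mean of 9.67 and a highest of 24, but these still held pairs from one gene family, such as Pilra and Pilrb1, and without predicted names and 3 family pairs 30 were found against a highest of 21. A gain or loss of whole chromosomes was not seen, since the largest absolute chromosome median was 0.0777 (log2) against 0.585 for 1 extra copy in every cell. Shorter copy number changes and regulation shared within a region were not tested.

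The TGF-b cultures carried Cdh1 at 90.4% and Krt8 at 63.7% of the untreated level together with high Vim and Zeb1. A mixture of converted and unconverted cells in such shares would keep every abundant untreated transcript, but 59 of the 5988 genes with an untreated mean of at least 1000 kept under 1%, and the 0 reads of Ap1m2 allow at most 0.0291%. Fibroblasts or stellate cells as the source of Vim are argued against by their abundant transcripts, with a median over Col1a1, Col1a2, Col3a1, Dcn, Lum and Sparc of 0.00169% of the Vim level, although Sparc reached 2.81%. One cell population that holds part of both programmes after TGF-b may explain this, but the libraries pool many cells and whether single cells carry both was not tested. Outgrowth of a few cells present before the exposure, and drift over the 4 weeks in culture, for which the labels give no matching time in the untreated cells, were not tested and stay open.

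The G1/S and G2/M genes, 50 in all, were lower in TGF-b libraries with a median log2 fold change of −1.31. After correction for GC content and transcript length 50 of 50 were still lower past the threshold, with a median of −1.32, so that bias was not the whole cause. Scaling between libraries is also argued against, because the median lay −1.33 from that of 6920 other genes of similar expression. This comparison and the random lists that follow restate the fall of these genes relative to other genes, and are not separate evidence of it. Of 10000 random lists matched on expression, 0 were as low (lowest median −0.33). Their genes were drawn independently, whereas the estimated correlation was 0.31 among G1/S and 0.75 among G2/M genes, so the random range may be too narrow. A lower share of dividing cells after TGF-b may explain this, but that share was not measured. Cell density and time since feeding at harvest, which could also lower these genes, were not tested.

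Heart muscle transcripts were found in untreated B, led by Myh6 with 650 reads. RNA or reads from heart tissue are a candidate source, since 22 of 24 heart genes held out from the discovery were higher in untreated B than in untreated A and C, against a mean of 7.55 and a highest of 16 in 10000 random lists matched on untreated reads. The others were Cox7a1 and the myosin light chain gene Myl2, which had 0 reads in all 6 libraries. Myl3 and Myh7 had only 3 and 10 reads in untreated B. Which part of the heart could be the source was not tested. The count of 22 takes any excess, however small. At least 8 reads and over 3 times the mean of untreated A and C were found for 8, against a highest of 3 in random lists. Of the 24, 7 had a mean of at least 10 in the other 5 libraries as well, among them Tnnt2. Mixing with another of these libraries is argued against by the 0 reads of Myh6 in the other 5. No biological explanation was tested, and where the transcripts entered stays open.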
